A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

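Messenger RNA of the fission yeast Schizosaccharomyces pombe was measured by RNA sequencing in 6 libraries, 3 of the wild type and 3 of a dsk1 mutant. Samples were grouped by the genotype in the labels. The series text describes the mutant as a deletion and the genotype label as a knockdown, so it is called the dsk1 mutant here. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected with oligo(dT), and the cDNA was amplified by PCR and sequenced. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

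The submitters' processing notes name fastp, Bowtie2, HISAT2, StringTie, RSEM and DESeq2, with no version, role or order. The genome build and the use of strand in counting are not given in the sources used here. Per the file headers, the authors deposited a count and an FPKM value (fragments scaled by gene length and library total) for each gene and library. The deposited counts are whole numbers, and how they became whole is not stated. The deposited table also holds the authors' log2 fold change, p-value and adjusted p for the comparison. Recomputed from the deposited FPKM, that log2 fold change is the log2 ratio of the group means, with means of 0 set to 0.001. A second deposited table holds the 135 genes with an authors' adjusted p under 0.05 and at least a 2-fold change.

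The full table has 5160 entries, of which 5136 carry a systematic gene name and 24 are loci assembled by the authors. RefSeq assembly ASM294v3 matched 5109 of them and was used for gene names, introns, exon length, neighbours, overlaps and distance to a chromosome end. No coordinates are given, since the authors' build is unknown. Library totals were 15700362 to 19020530 counts. A count of 3 in a library, taken as the floor for a count of 0, is 0.158 to 0.191 CPM (counts scaled to the library total). Floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules, while the interval given for dsk1 comes from the fit and holds the spread between libraries. No library was a copy of another, as the counts of every replicate pair differed by more than sampling noise, with a chi-square per degree of freedom of 26.7 to 280.

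Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the default expression filter and genotype as the only term. The filter kept 4987 genes and left out 173, of which 45 had no count in any library. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p for a gene comes from this test. Log2 fold changes are mutant over wild type, with a standard error (SE) from the fit and a residual spread shared across genes. Levels are TMM-scaled CPM as mean and SD of 3 libraries. On simulated counts with these means and library sizes, over 4984 genes, the test recovered 15 of 67 genes changed 1.5-fold (22.4%). It recovered 47 of 67 changed 2-fold (70.1%) and 64 of 66 changed 4-fold (97.0%). A further set of genes, raised 1.5-fold to try camera, is not in these shares. That set was recovered less often, so the share of all genes changed 1.5-fold was below 22.4%. There, 11 of the 140 calls were false. The simulation drew each gene independently, with no outlying library and no trend with length, so these shares need not hold for the real libraries.

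Gene lists on 25 subjects were fixed before the data were examined, and 24 were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01. They cover DNA repair and replication, splicing and mRNA export, translation, metabolism, stress, sexual differentiation, septation, histones, transposons, adhesins, introns and chromosome ends. A list of strain markers was given as single genes only. Adjusted p for lists is over the 24 lists. Beside it, each list has counts of members called over all genes tested and of members called when adjusted over the list alone. Camera was repeated with a correlation estimated for each list, and fry was run in its place. Annotated GO and KEGG terms of 10 to 500 tested genes were examined among called genes with a one-sided Fisher exact test. Of the names written into the lists, 8 matched no gene.

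The rule for naming genes was also fixed beforehand. It took dsk1 and rad52, then the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries, then up to 4 members of each list with the smallest adjusted p, and called strain markers. Other genes are said to have been chosen after their values were seen. Alternatives were other scaling factors, other filters, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1 or for all genes, a stricter threshold, a block for the replicate number, and each library left out. A fit with the trend of each library on exon length removed, and a retrotransposon list with genes of equal counts entered once, were chosen after seeing the data.

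Sequence shared between genes was measured as the share of a gene's 50-base words found elsewhere in the assembly. It reached 10% or more in 114 tested genes, and reads of these genes cannot be assigned with certainty. Of the 101 called genes, 19 had at least 30% of their span covered by a gene on the other strand. None of the 19 partners was called in edgeR (0 called, 6 at an unadjusted p under 0.05, and 1 called in DESeq2). As the use of strand is not stated, reads of such pairs cannot be told apart, and these genes are given as uncertain. The same limit holds for 11 named genes that were not called, cdm1, spk1, his3, his4, cwf24, rrp2, cct2, rad4, spo12, nrm1 and cig2. Fold changes against a group with 0 counts in each library were computed against the floor of 3 counts per library.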

Results

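Transcript levels were measured in 6 libraries of poly(A)-selected RNA from whole fission yeast cells, 3 from the wild type and 3 from a mutant of dsk1, which encodes a kinase of SR splicing proteins. The wild-type libraries held 16424139, 16621420 and 18039520 counts and the mutant libraries 19020530, 17517270 and 15700362 counts. The 10 most abundant genes took 6.52% to 8.17% of a library. On the first principal component, with 60.1% of the variance, wild-type replicate 2 stood at -37.9, the other wild-type libraries at -9.54 and -2.29, and the mutant libraries between 13.1 and 19.6. The study's title concerns Dsk1, Rad52 and repair of double-strand breaks by homologous recombination, and the comparison asks which transcripts differ between the dsk1 mutant and the wild type.

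The dsk1 transcript (SPBC530.14c) fell in the mutant by 3.03 on the log2 scale (SE 0.13, adjusted p = 1.34e-04), an 8.17-fold decrease. Its level was 99.4, 102 and 99.96 CPM in the wild-type libraries and 13.7, 11.3 and 11.9 CPM in the mutant libraries. The reads left in the mutant were 12.2% of the wild-type level (95% interval 9.92% to 15.1%). A gene on the other strand, lsc1, covers 34.1% of dsk1 and had 23.7 CPM in the mutant, so the reads left over cannot be assigned with certainty. The transcript of rad52, a homologous recombination gene, was at 46.3 ± 0.82 CPM (SD, n = 3) in the wild type and 62.8 ± 3.69 CPM (SD, n = 3) in the mutant. This 1.36-fold difference, a log2 fold change of 0.44 (SE 0.11), was in the same direction in each of the 3 mutant libraries and did not pass the test (adjusted p = 0.0908). It passed with the DESeq2 Wald test and without wild-type replicate 2 (log2 fold change 0.44 and 0.45), and its adjusted p ranged from 0.00768 to 0.368 over the alternatives.

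In all, 101 of the 4987 genes tested were called, 22 higher and 79 lower in the mutant, and 56 of them changed at least 2-fold, 14 higher and 42 lower. The largest rise was that of ura4, which encodes orotidine monophosphate decarboxylase and is widely used as a selectable marker to replace genes. It had 0 counts in each wild-type library and 1957, 1392 and 1710 counts in the mutant libraries, 96.2 ± 20.2 CPM (SD, n = 3), at least 545-fold higher (adjusted p = 5.54e-04). The labels give no strain genotype beyond dsk1, so no difference between the groups can be assigned to dsk1 alone. The metallothionein gene zym1 rose 2.81-fold, from 63.9 ± 15.73 to 180 ± 21.8 CPM (SD, n = 3, adjusted p = 0.0208). The oligopeptide transporter gene isp4 rose 2.73-fold, from 47.9 ± 3.32 to 131 ± 46.2 CPM (SD, n = 3, adjusted p = 0.0426). The gene of unknown function SPBC1685.17 rose 2.60-fold to 46.1 CPM (adjusted p = 0.0208), and ctu2, for a subunit of the enzyme that thiolates tRNA, rose 2.45-fold to 43.8 CPM (adjusted p = 0.0295). The splicing factor gene tls1 rose 2.22-fold, from 40.1 ± 5.22 to 89.1 ± 8.997 CPM (SD, n = 3, adjusted p = 0.0208), but 91.9% of it is covered by grh1 on the other strand, so its counts are uncertain. The same holds for the pumilio family gene mpf1, up 2.23-fold and covered by chz1 over 93.8% of its span, and for SPBC21D10.08c, up 2.24-fold and covered by cmc1 over 76.6%. Assembled loci annotated as RecQ helicases of the Tlh1 kind, a subtelomeric family with near-identical copies, rose 3.88-fold (MSTRG.4827, to 29.3 CPM) and 3.19-fold (MSTRG.4826, to 27.4 CPM).

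**Figure D1:**
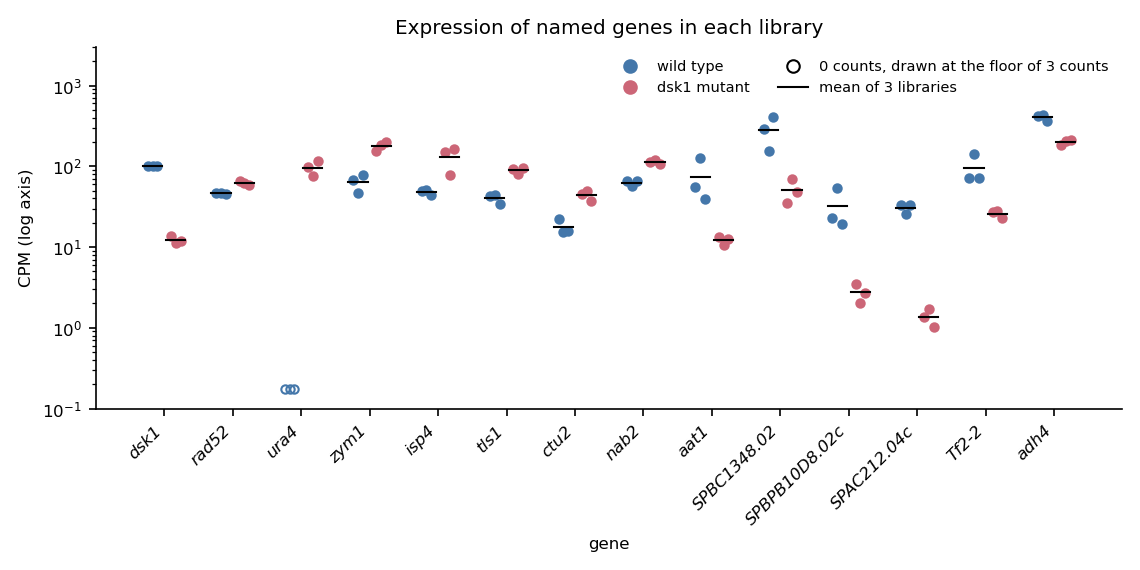
Expression of 14 genes in each library, in CPM on a log axis; points are libraries, bars are means of 3 libraries, and open circles are 0 counts drawn at the floor of 3 counts. For dsk1 the mutant libraries lie between 11.3 and 13.7 CPM and the wild-type libraries between 99.4 and 102 CPM, while ura4 had no count in the wild type.

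Many of the deepest falls were in genes near chromosome ends, several of them in families of near-identical copies. The DUF999 family genes SPBCPT2R1.01c, SPAC212.04c and SPBCPT2R1.04c fell 26.0-fold (from 22.2 CPM), 22.3-fold (from 30.8 CPM) and 21.2-fold (from 22.8 CPM), and SPBC1348.01 fell 5.36-fold, with adjusted p between 3.99e-04 and 0.0208. For SPBCPT2R1.04c the log2 fold change was -4.40, and -5.19 without mutant replicate 2. In the opposite direction SPAC212.01c, another DUF999 gene, had 0 counts in the wild type and 52, 44 and 23 counts in the mutant libraries, at least 12.3-fold higher. Since reads of such copies cannot be assigned with certainty, the family sum is given too, and over 9 tested DUF999 genes it was 112 ± 27.5 CPM (SD, n = 3) in the wild type and 46.7 ± 11.04 CPM (SD, n = 3) in the mutant. Among genes of the 5Tm membrane protein family, SPBPB2B2.19c fell 29.6-fold, from 68.3 ± 29.9 to 2.24 ± 1.91 CPM (SD, n = 3, adjusted p = 0.0315; log2 fold change -4.89, and -5.50 without mutant replicate 2), and SPBC1348.02 fell 5.53-fold. The sum over 5 tested members of that family was 419 ± 194 CPM (SD, n = 3) in the wild type and 70.6 ± 22.0 CPM (SD, n = 3) in the mutant. As the counting of reads shared by several copies is not stated, neither the DUF999 nor the 5Tm sum is a certain family total. The predicted arylsulfatase gene SPBPB10D8.02c, which has sequence of its own, fell 11.7-fold, from 32.3 ± 19.4 to 2.75 ± 0.74 CPM (SD, n = 3, adjusted p = 0.0208; log2 fold change -3.55, and -2.94 without wild-type replicate 2). The amino acid transporter gene aat1 fell 6.07-fold, from 74.4 ± 47.3 to 12.2 ± 1.40 CPM (SD, n = 3, adjusted p = 0.0343), with 128 CPM in wild-type replicate 2 against 55.7 and 39.4 CPM in the other wild-type libraries (log2 fold change -2.60, and -1.95 without that library). The assembled locus MSTRG.4330 fell 10.8-fold from 6.10 CPM. The meiotic gene mug97 had 0 counts in the mutant against 108, 108 and 48 in the wild type, at least 31.2-fold lower, but it lies within mug57 on the other strand and is uncertain.

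Of the 101 called genes, all had no overlap between the libraries of the groups, as did 32.1% of all tested genes. Chance gives 10% on average over splits of the libraries. Genes vary together, so the share in a single split can lie far from that, and no conclusion is drawn from it. The number of calls changed with every library left out. It was 11, 466 and 179 without wild-type replicates 1, 2 and 3, and 5, 7 and 3 without mutant replicates 1, 2 and 3. Such a fit also has fewer libraries to estimate the spread, and this was not separated from the weight of a given library. The genes called in each of these 6 fits were dsk1, ura4 and SPAC212.04c. All 101 kept their direction in every one, which follows from their lack of overlap and is no separate support. The DESeq2 Wald test called 568 genes, among them all of the 101.

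**Figure D2:**
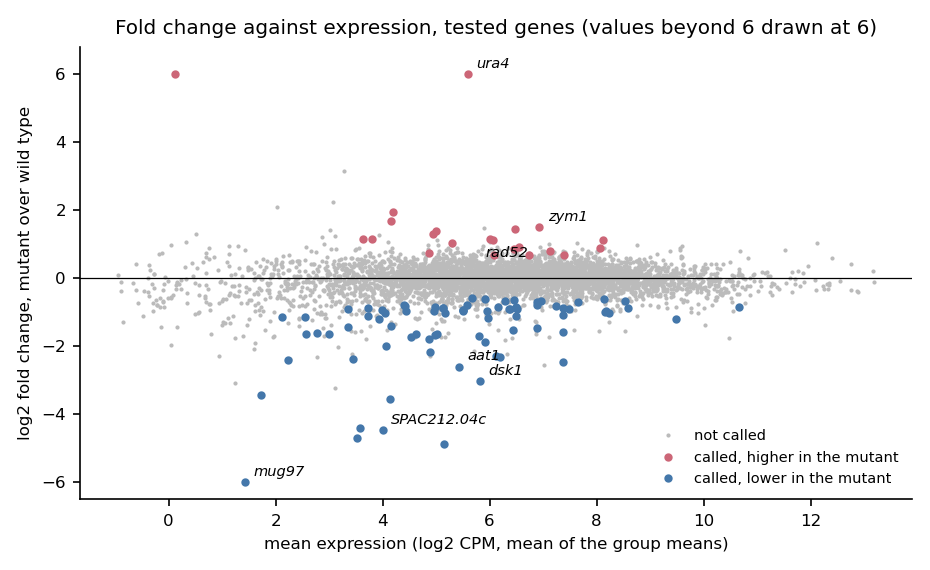
Log2 fold change of mutant over wild type against mean expression in log2 CPM, one point per tested gene, with 22 called higher genes in red, 79 called lower genes in blue and values beyond 6 drawn at 6. Called genes lie below 0 more often than above it.

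Genes within 100 kb of a chromosome end fell as a group, with a median log2 fold change of -0.22 over 151 tested genes (camera, adjusted p = 3.49e-05; adjusted p = 0.256 with an estimated correlation). The correlation estimated for this list was 0.0123, close to the preset 0.01, while the unadjusted camera p went from 1.46e-06 to 0.0107. A higher correlation between the genes thus does not account for the lost call, and the camera settings differ in more than that value. Of these, 1 rose, 15 fell and 135 did not pass, and 29 fell and 4 rose when adjusted over the list alone, the last including nnk1 at 0.60, pal1 at 0.48 and put4 at 0.77, chosen after their values were seen. The list of Tf2 retrotransposons and subtelomeric helicases, with 10 Tf2 genes and the helicase gene tlh2 tested, had a median of -0.55 (camera, adjusted p = 0.00101; adjusted p = 0.770 with an estimated correlation). Tf2-3, Tf2-5, Tf2-6 and Tf2-12 have the same counts in each library, so 1 measurement entered 4 times and set that median. With it entered once the median was -0.86 over 8 genes (camera, adjusted p = 0.00667). With an estimated correlation the camera p of this shorter list was 0.0465 before adjustment over the lists. The helicase went the other way, with tlh2 at 0.79 without passing and the assembled loci MSTRG.4827 and MSTRG.4826 called higher. Tf2-2 fell by 1.89 on the log2 scale, from 95.5 to 25.7 CPM, and Tf2-7 fell by 1.66, from 48.2 to 15.2 CPM. The other 9 did not pass, among them Tf2-10 at -1.18 and Tf2-11 at -1.66 (-2.55 without mutant replicate 1), and 4 fell when adjusted over the list alone. Tf2 copies are near-identical, and the sum over 10 copies was 319 ± 13.9 CPM (SD, n = 3) in the wild type and 171 ± 42.4 CPM (SD, n = 3) in the mutant. The measurement shared by Tf2-3, Tf2-5, Tf2-6 and Tf2-12 enters this sum 4 times. How reads of several copies were counted is not stated, so the sum is not a certain family total. The list of cell surface adhesins was not called (11 tested, median -0.14, mean -0.52, adjusted p = 0.102), and its median was 0.050 without wild-type replicate 2. Its member pfl9, a predicted flocculin-like glycoprotein, fell by 1.79 on the log2 scale, from 45.2 to 13.0 CPM (adjusted p = 0.0227), 2 members fell when adjusted over the list alone, and pfl7 was at -3.08, pfl6 at -0.74 and fta5 at 0.31 without passing over all genes. For pfl7 wild-type replicate 2 had 8.67 CPM against 2.44 and 1.54 CPM, and it passed without that library (-2.01) or wild-type replicate 3 (-3.49).

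Amino acid biosynthesis genes were lower as a group, with a median log2 fold change of -0.36 and 35 of 38 members below 0 (camera, adjusted p = 1.40e-04; adjusted p = 0.770 with an estimated correlation). With edgeR 0 members were called, also when adjusted over the list alone, 17 were lower at an unadjusted p under 0.05, and DESeq2 called 7 and limma 1. The arginine genes arg12, arg5 and arg6 were at -1.005, -0.76 and -0.48, and the histidine gene his4 at -0.83. In wild-type replicate 2 arg12 had 1506 CPM, against 1016 and 959.97 CPM in the other wild-type libraries. The hexose transport and glycolysis list fell, with a median of -0.26 over 28 genes (camera, adjusted p = 0.0187; adjusted p = 0.770 with an estimated correlation). In it 1 gene was called, also when adjusted over the list alone. This was adh4, a mitochondrial alcohol dehydrogenase, which fell by 1.02 on the log2 scale, from 403 ± 33.2 to 198 ± 14.3 CPM (SD, n = 3, adjusted p = 0.0205). The other 27 did not pass, among them the hexose transporter ght1 at -1.05, the enolase gene eno102 at -0.41 and the glyceraldehyde phosphate dehydrogenase gene gpd3 at 0.60. The list was not called without wild-type replicate 2 (median -0.13) or mutant replicate 1 (median -0.21).

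The respiration and TCA cycle list fell, with a median of -0.16 over 61 genes (camera, adjusted p = 0.0148; adjusted p = 0.782 with an estimated correlation), of which 3 fell and 58 did not pass, while 1 rose (SPBC3H7.03c, at 0.63, chosen after its value was seen) and 6 fell when adjusted over the list alone. The complex III genes qcr10 and qcr9 fell by 0.89 and 0.68 on the log2 scale (adjusted p = 0.0295 and 0.0379), and cox17, a copper chaperone of cytochrome oxidase, fell by 1.14 (adjusted p = 0.0358). The ATP synthase gene atp20 was at -0.66 without passing. Reads of qcr9 are uncertain, as mcm3 covers 77.3% of it on the other strand. Cytoplasmic ribosomal protein genes were lower as a group, with a median of -0.19 and 110 of 138 members below 0 (camera, adjusted p = 0.00667; adjusted p = 0.868 with an estimated correlation). There rps3002 fell by 0.91 (adjusted p = 0.0403), with 50.2% of it covered by abz2, the other 137 did not pass, and rpl39, rps2502 and rps1102 were at -1.12, -0.57 and 0.47. Adjusted over the list alone, 0 were called by edgeR, against 3 higher and 16 lower at an unadjusted p under 0.05, while DESeq2 called 2 higher and 6 lower and limma 2 lower over all genes. Both lists hold short transcripts, with median exon lengths of 1131 and 606 bases against 1711 in all tested genes. The genes called lower had a median of 1321 bases. Across genes, which are not independent replicates, log2 fold change increased with exon length (Spearman 0.257), and counts per gene tended to longer transcripts in mutant replicates 1 and 2 (Spearman 0.306 and 0.303) but not in mutant replicate 3 (-0.07). Ribosomal protein genes were not called without wild-type replicate 2 (median -0.03) or mutant replicate 2 (median -0.11), nor respiration genes without wild-type replicate 2 (-0.10), wild-type replicate 3 (-0.20), mutant replicate 1 (-0.14) or mutant replicate 2 (-0.14). The single calls in these lists also depended on the length trend. With that trend removed, 0 ribosomal protein genes were called lower and 1 higher. In the same fit 1 respiration gene was called lower and 0 higher.

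Lists on protein folding, stress and nutrient uptake were not called. The 27 chaperone genes had a median of -0.22 (adjusted p = 0.0565) and 0 edgeR calls, also when adjusted over the list alone, with 6 lower at an unadjusted p under 0.05 and 1 each in DESeq2 and limma. Among them mge1 was at -0.56, mas5 at -0.45, cct2 at -0.40 and ssa1 at -1.56 (-0.84 without wild-type replicate 2, which had 700 CPM against 218 and 261 CPM, and -2.29 without mutant replicate 3). The list was called without wild-type replicate 1 (median -0.25) or mutant replicate 3 (median -0.35). In the core environmental stress response (31 genes, median -0.22, adjusted p = 0.765), zym1 rose, also when adjusted over the list alone, and 30 did not pass, among them atf1 at 0.40, hsp9 at 0.59 and trr1 at -0.61. Its median and mean (-0.13) lay below 0 while camera pointed upward, and camera pointed downward without wild-type replicate 1 (median -0.22), wild-type replicate 3 (median -0.24) or mutant replicate 3 (median -0.29). For iron, copper and zinc uptake (16 genes, median -0.03, adjusted p = 0.802), edgeR called 0, with 1 higher and 3 lower at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma. Adjusted over the list alone 1 fell, and the iron permease gene fip1 was at -0.95, its oxidase fio1 at -0.52, fep1 at -0.45 and zrt1 at 0.33. Without wild-type replicate 3 that median was 0.05. For phosphate acquisition (6 genes, median -0.14, adjusted p = 0.758) edgeR, DESeq2 and limma called 0, also when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. The values were -0.52 for tgp1, -0.65 for pho84, 0.28 for vtc4 and -0.19 for csk1. For ribosome biogenesis (64 genes, median -0.03, mean -0.01, adjusted p = 0.758) camera pointed upward against the sign of both, and downward without wild-type replicate 3 (median -0.09). EdgeR called 0 there, also when adjusted over the list alone, with 3 higher and 2 lower at an unadjusted p under 0.05 and 1 in each direction in DESeq2. Its leading members were rrp2 at 0.59, rpa43 at -0.44, rrp1 at -0.47 and rrp9 at 0.38. The rrp genes entered this list through a pattern on the symbol, which does not show that rrp1 or rrp2 acts in ribosome biogenesis.

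The DNA repair and replication lists were not called. Of 40 homologous recombination genes 28 lay above 0, with a median of 0.15 (camera, adjusted p = 0.282), and edgeR called 0, also when adjusted over the list alone, with 3 higher and 4 lower at an unadjusted p under 0.05, 1 in each direction in DESeq2 and 0 in limma. Besides rad52, the helicase gene fml1 was at 0.39, rad55 at 0.41 and nse4, of the Smc5-Smc6 complex, at -0.53. For end joining and the damage checkpoint (20 genes, median 0.09, adjusted p = 0.654) edgeR called 0, also when adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05 and 1 in each direction in DESeq2. The checkpoint mediator crb2 was at 0.49, rad4 at 0.33, xlf1 at 0.56 and swi3 at -0.57, and without wild-type replicate 2 the list's median was -0.13. For excision, mismatch and post-replication repair (35 genes, median 0.06, adjusted p = 0.802) edgeR called 0 over all genes, with 1 higher and 4 lower at an unadjusted p under 0.05 and 2 lower in DESeq2. Adjusted over the list alone 2 fell, the post-replication repair gene ubc13 (-0.75) and the translesion polymerase gene kpa1 (-0.63), while rev1 was at -0.44 and uve1 at 0.33. Camera pointed downward for that list without wild-type replicate 2 (median 0.05), mutant replicate 1 (median 0.03) or mutant replicate 2 (median -0.01). DNA replication (45 genes, median 0.17, adjusted p = 0.102) had 0 edgeR calls, also when adjusted over the list alone, 4 higher and 1 lower at an unadjusted p under 0.05 and 2 higher in DESeq2, with the polymerase delta subunit gene cdm1 at 1.23 (uncertain, as sad1 covers 100% of it on the other strand), mcm2 at 0.49, mcm6 at 0.54 and orc5 at -0.78. Without mutant replicate 3 the recombination and replication lists were called, with medians of 0.18 and 0.20. Among 13 transcripts of the G1-S regulator MBF (median 0.17, adjusted p = 0.654) edgeR, DESeq2 and limma called 0, also when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05, and yox1 was at -0.68, mik1 at -0.34, cig2 at 0.22 and nrm1 at 0.17. The MBF median was 0.051 without wild-type replicate 2 and 0.070 without mutant replicate 2.

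**Figure D3:**
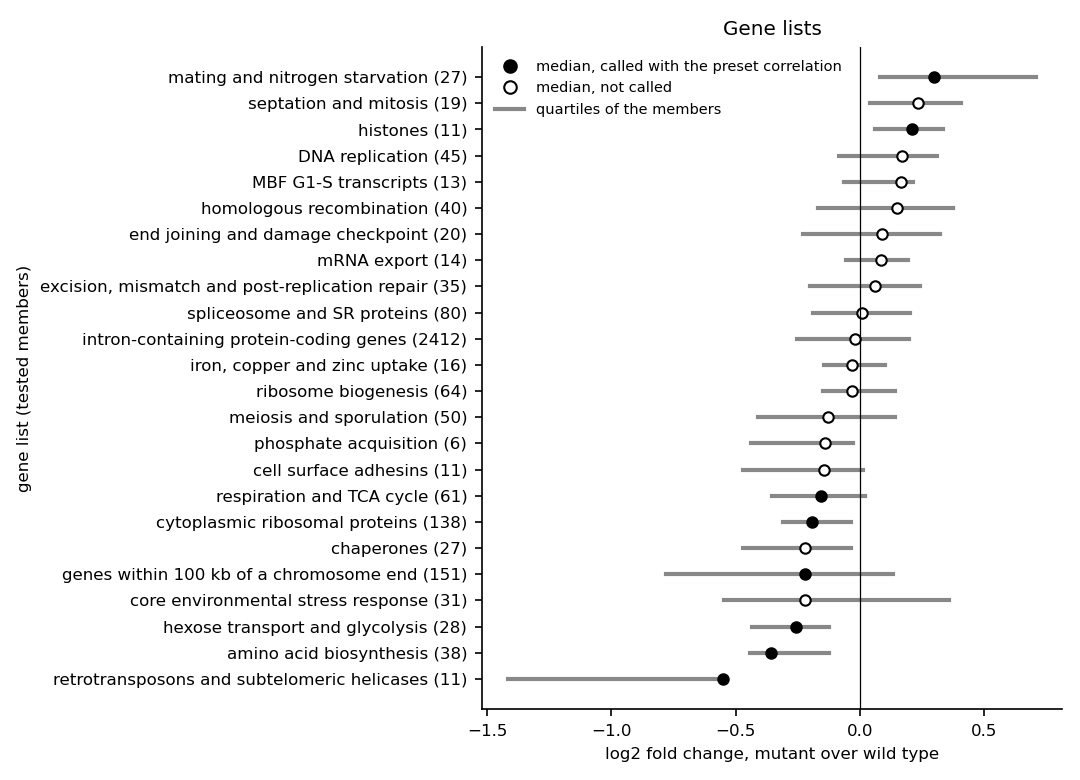
Median log2 fold change of mutant over wild type for 24 gene lists, with the quartiles of the members as grey lines, the number of tested members in brackets and filled points for the 8 lists called with the preset correlation. Homologous recombination had a median of 0.15 and was not called.

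Dsk1 phosphorylates SR proteins, so splicing and mRNA export genes were examined too. Of the 80 spliceosome and SR protein genes (median 0.01, adjusted p = 0.739) edgeR called 0, also when adjusted over the list alone, with 9 higher and 11 lower at an unadjusted p under 0.05, 3 higher and 4 lower in DESeq2 and 0 in limma. The leading members were usp109 at -0.55, cwf24 at -0.51, smg1 at -0.70 and cwf10 at 0.36. In the mRNA export list (14 genes, median 0.09, adjusted p = 0.282) nab2, which encodes a poly(A) binding protein, rose 1.81-fold, from 62.4 ± 4.81 to 113 ± 6.65 CPM (SD, n = 3, adjusted p = 0.0208), also when adjusted over the list alone. The other 13 did not pass, among them tho2 at 0.32, sac3 at 0.29 and crp79 at 0.16. The 2412 tested genes with introns had a median of -0.02 (adjusted p = 0.282), and 5 of them rose and 39 fell, or 5 and 33 when adjusted over the list alone. The pyruvate dehydrogenase component gene pdx1 fell by 1.09 on the log2 scale, from 226 ± 17.6 to 106 ± 6.02 CPM (SD, n = 3, adjusted p = 0.0117), and this list was called without wild-type replicate 2 (median -0.04).

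Mating and nitrogen starvation genes were higher as a group, with a median of 0.30 and 21 of 27 members above 0 (camera, adjusted p = 0.0132; adjusted p = 0.770 with an estimated correlation). In this list isp4 rose, mei3, whose product triggers meiosis by inhibiting the Pat1 kinase, fell by 1.64 on the log2 scale from 12.2 to 3.89 CPM (adjusted p = 0.0358), and 25 did not pass. Adjusted over the list alone 1 fell and 4 rose, among them isp7 at 0.96, the MAP kinase gene spk1 at 1.11 (uncertain, as ups1 covers 77.3% of it on the other strand) and, chosen after its value was seen, mam1 at 0.67. Histone genes were higher as a group, all 11 above 0 with a median of 0.21 (camera, adjusted p = 0.0439; adjusted p = 0.770 with an estimated correlation). EdgeR called 0 of them, also when adjusted over the list alone, with 3 higher at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma, and the values were 0.42 for pht1, 0.48 for hhf1, 0.32 for hhf3 and 0.31 for hta2. The histone list was not called without wild-type replicate 1 (median 0.26), wild-type replicate 3 (0.26), mutant replicate 2 (0.24) or mutant replicate 3 (0.23). For septation and mitosis (19 genes, median 0.23, adjusted p = 0.0676) edgeR called 0, also when adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, 2 higher in DESeq2 and 1 in limma. Here cfh4 was at 0.52, the glucanase genes agn1 at 0.48 and adg3 at 0.36, and spo12 at 0.60. That list was called without wild-type replicate 2 (median 0.20) or mutant replicate 3 (median 0.35). For meiosis and sporulation (50 genes, median -0.13, adjusted p = 0.282) edgeR called 0 over all genes, with 1 higher and 10 lower at an unadjusted p under 0.05, 6 lower in DESeq2 and 1 in limma. Adjusted over the list alone 4 fell, and the meiotic cohesin gene rec8 was at -0.87, meu17 at -0.87, meu31 at -0.85 and meu10 at -0.61. Of 17 tested strain marker and mating-type genes ura4 alone was called over all genes, and 2 rose (ura4, mam1) and 3 fell (arg3 at -0.85, leu1 at -0.83, his3 at -0.46) when adjusted over the list alone, the last 4 chosen after their values were seen, while 6 were called without wild-type replicate 2 and 3 without wild-type replicate 3.

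With an estimated correlation 0 of the 24 lists kept their call in camera, with 1 at an unadjusted p under 0.05, and fry called 2, chromosome ends and mRNA export. Among the called lists the estimate was 0.0123 for chromosome ends and from 0.0637 (mating) to 0.756 (ribosomal proteins) for the others. Of 1610 tests of GO and KEGG terms among called genes, 0 passed in the one-sided Fisher exact test, 24 had an unadjusted p under 0.05, and 0 passed among genes changed at least 2-fold, with 16 at an unadjusted p under 0.05. The log2 fold changes from edgeR and those of the authors' deposited table had a Pearson correlation of 0.994 and a Spearman correlation of 0.999 across 4987 genes, which are not independent replicates. Both sets of values come from the same 6 libraries, so a high correlation was given beforehand. The authors' deposited table has 568 genes with an adjusted p under 0.05, among them all 101 called here, and its 135 genes of at least 2-fold change comprise 26 higher and 109 lower. Its adjusted p for dsk1 (4.60e-92) and rad52 (0.00768) equal those of the DESeq2 Wald test run here, which also called 568 genes. The 2 counts are thus 1 result and no separate support.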

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

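The search for genes outside the comparison was chosen only after the low-count genes had been seen. Of the 173 genes that the expression filter left out, 6 had at least 10 counts in wild-type replicate 2 and 0 counts in the 5 other libraries. The reported comparison left these genes out, though some alternatives tested them. The counts were 96 for cum1, 64 for dut1, which encodes dUTPase, 38 for SPCC569.04, 34 for SPAC6C3.05, 29 for SPAC922.06 and 12 for mde7. No explanation was tested, and the counts alone do not show whether these transcripts were absent from the 5 other libraries.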

How the results depend on the processing

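The fit with the length trend removed and the retrotransposon list with equal counts entered once (median -0.86, still called at the preset correlation) were chosen after the data were seen. The other alternatives were fixed before. In every alternative dsk1 was called, with a log2 fold change of -3.14 to -2.70. The 101 called genes were all tested in every alternative except a filter at 5 CPM, which tested 97. Each kept its direction where tested, which their lack of overlap between the groups' libraries would give by itself. Of 1700 values for 107 named genes, 1443 kept their side of the threshold, 158 lost the call, 99 gained it and 0 changed sign. Most of these genes were not called here, so keeping their side mostly meant staying uncalled. Among the called ones, zym1, tls1, nab2 and adh4 passed in 2 of the fits with a library left out. The genes ura4 and SPAC212.04c passed in all 6. Of 449 values for gene lists, 380 were the same, 30 lost a call, 18 gained one, 12 changed the direction of the set test (3 of them also the sign of the median) and 9 counts moved. The cause was not tested unless stated. Calls numbered 101 here, 568 with DESeq2, 5 at an adjusted p under 0.01 (a stricter threshold) and 3 to 466 with a library left out. At 2-fold or more they numbered 56, 143 with DESeq2 and 3 to 122 with a library left out. Of the calls 78.2% were lower here, 83.6% of 122 with upper-quartile scaling, 63.9% with DESeq2 and 64.6% without wild-type replicate 2. The value of rad52 passed with DESeq2 (0.44) and ranged from 0.39 to 0.48 with a library left out. Labels number the replicates alike in both groups, but same-numbered libraries did not deviate together (correlations 0.17, -0.36 and -0.19). With the replicate number as a block, 3 genes were called, 3 of them at 2-fold or more, 0 strain markers in edgeR (6 at an unadjusted p under 0.05), and the histone list (median 0.24) was not. Medians of lists do not change with the set test, and calls ended with an estimated correlation at -0.22 for chromosome ends, and with that and with fry at -0.19 for ribosomal proteins, 0.30 for mating, -0.26 for hexose, -0.16 for respiration, -0.36 for amino acids, -0.55 for retrotransposons and 0.21 for histones. With fry mRNA export (0.087) was called. Chaperones were called with upper-quartile factors (-0.24), the filter at 5 CPM (-0.22), limma with a pseudocount of 1 (-0.17), of 0.1 (-0.17) or no filter (-0.17), and the length trend removed (-0.27). Septation was called with limma (0.25, 0.26 and 0.25). The test of the stress response changed direction with limma (-0.075 and -0.076). With the length trend removed ribosomal proteins (-0.036) and respiration (-0.088) lost the call, adhesins (-0.33) gained it, and the test of excision repair changed direction (0.011). That fit called 96 genes, 81 of them among the 101. Called strain markers numbered 1 here, 6 with DESeq2, 3 with upper-quartile factors, the 5 CPM filter and each of the 3 limma settings, and 1 to 6 with a library left out. With a library left out, medians ranged from 0.093 to 0.20 for recombination, -0.13 to 0.26 for the checkpoint, -0.0052 to 0.19 for excision repair, 0.083 to 0.20 for replication, -0.29 to 0.092 for stress, -0.30 to -0.029 for ribosomal proteins, -0.085 to 0.051 for ribosome biogenesis, -0.12 to 0.052 for iron, -0.35 to -0.091 for chaperones, -0.38 to -0.13 for hexose, -0.25 to -0.10 for respiration, 0.14 to 0.35 for septation, 0.23 to 0.30 for histones, -0.041 to 0.0055 for introns, -0.26 to 0.050 for adhesins, 0.051 to 0.19 for MBF, 0.039 to 0.14 for mRNA export, -0.15 to -0.052 for meiosis, -0.21 to -0.083 for phosphate, -0.0020 to 0.040 for the spliceosome, -0.67 to -0.36 for retrotransposons, 0.20 to 0.39 for mating, -0.41 to -0.24 for amino acids and -0.29 to -0.18 for chromosome ends. Depth limits what can be seen below 0.158 to 0.191 CPM, the level of 3 counts in a library.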

Other observations

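The tests of explanations in this part were chosen after the results were seen, except those on other splits of the libraries, and so were the genes named in the next paragraph. The test of each gene, the term tests and the fits with a library left out were fixed before.

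Some further called genes are given here as single genes. Terms that hold them did not pass, with an adjusted p of 1 for purine nucleotide biosynthesis (unadjusted p = 0.0251) and for protein import into the mitochondrial matrix (unadjusted p = 0.0341). Lower in the mutant were ser3, the first enzyme of serine synthesis, from 997 to 433 CPM (log2 fold change -1.20, adjusted p = 0.0461), thf1, the trifunctional enzyme of one-carbon metabolism (-0.61), the purine synthesis gene ade2 (-0.98), the guanine deaminase gene gud1 (-0.81) and fol2 (-0.64), which acts in folate synthesis. The phosphatidylethanolamine methyltransferase gene cho2 was lower (-0.68), and the inositol transporter gene itr1 higher (0.69, from 128 to 206 CPM). Of the mitochondrial import receptor complex, tom5 (-0.88) and tom7 (-0.72) were lower, though tom7 is covered over 91.7% by sip1 on the other strand. The gene of the MBF activator Rep2, rep2, fell from 96.4 ± 7.83 to 59.97 ± 3.06 CPM (SD, n = 3, adjusted p = 0.0354). With mutant replicate 3 left out, 3 genes were called in all, and none of these was among them.

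Transcripts near chromosome ends were lower, and among genes with under 10% of shared sequence 5 of 104 within 100 kb fell and 0 rose, 14 of 224 between 100 and 200 kb fell and 2 rose, and 46 of 4509 farther in fell, dsk1 among them, and 17 rose. The tables argue against reads shared between copies as the whole cause, because the 104 genes with sequence of their own were also lower (median -0.16, a camera p of 0.00627, and of 0.0416 with an estimated correlation). Both p-values are unadjusted. The full list of genes near chromosome ends was not called by camera with an estimated correlation (adjusted p = 0.256). For the 47 genes with shared sequence (median -0.78) sharing cannot be told apart from a fall, since counts per gene hold no read positions. A trend with transcript length is also argued against, as the list's median was -0.24 with the trend removed and -0.22 before. What lowers transcripts near the ends stays open, and a strain difference there was not tested. As a separate observation, genes called lower lay side by side. With dsk1 left out, 5 pairs of next neighbours both fell, where 10000 random draws of 64 of the 4836 genes gave 1.45 on average (one-sided permutation p = 0.0134). Each draw held as many genes in each of these bands of distance. Over 200 kb from an end, the 2 pairs against 0.456 on average (permutation p = 0.0780) leave open whether neighbouring genes fall together there.

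Ribosomal protein genes were lower by a median of -0.19 (quartiles -0.31 and -0.03). With the trend on exon length removed their median was -0.036 (quartiles -0.17 and 0.09) and the call ended because the median moved to near 0. That trend was fitted over all genes with a known length, these included, so a fall of short genes is partly removed with it. Without wild-type replicate 2, however, the median was also near 0 (-0.029) while the trend was nearly the same (Spearman 0.235 against 0.238 in genes outside the ribosomal protein and respiration lists), so length cannot be told apart from other causes. Among those genes the median was -0.09 in the 1189 shortest and 0.13 in the 1189 longest. For respiration genes the median went from -0.16 (quartiles -0.35 and 0.02) to -0.088 (quartiles -0.36 and 0.05), which loses the call while the quartiles still overlap widely, so length and genotype cannot be told apart there. Whether the trend itself is technical or biological was not tested.

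Of the dsk1 reads 12.2% were left in the mutant. Wild-type cells in the mutant cultures could leave them, and then no other transcript should fall further; 3 genes lie wholly below the interval of dsk1, SPAC212.04c and SPBCPT2R1.01c by their 95% intervals and mug97, with 108, 108 and 48 counts in the wild type and 0 in each mutant library, by its bound of at least 31.2-fold lower. These go against such cells, but the first pair share sequence with other genes and mug97 is covered over 100% by mug57 on the other strand, so 0 of the 3 have reads that can be assigned with certainty and this cannot be told apart. Reads of lsc1, which overlaps dsk1 and had 23.7 CPM in the mutant, could also be counted for dsk1, and a transcribed rest of the gene could be as low. Reads per position, which would separate these, were not used here.

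The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 101 genes, 56 of at least 2-fold, and the highest of the other splits 0 in both cases, so 1 split, the real one, reached each count. For gene lists the real split called 8 and the highest other 12, and 5 of the 10 splits called as many as the real one.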
